A study of Homo sapiens with 40 samples.

How the data were processed

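RNA was sequenced from HEK293T cells, a human embryonic kidney line, that expressed the engineered peroxidase APEX2 fused to 1 of 4 targeting sequences. The constructs were MITO (mitochondrial matrix), ERM (endoplasmic reticulum membrane), NES (cytosol, through a nuclear export signal) and LMNB1 (nuclear lamina, through lamin B1). APEX2 converts biotin-phenol and hydrogen peroxide into a short-lived radical that attaches biotin to nearby molecules. Per the labels' protocols, the thionucleoside 6-thioguanosine (s6G) or 4-thiouridine (s4U) was given at 100 uM for 5 h in all, with 0.5 mM biotin-phenol for the last 30 min and 1 mM hydrogen peroxide for 1 min. The APEX-only arms received no thionucleoside, and the unlabelled arms received neither thionucleoside nor biotin-phenol but still the peroxide. Biotinylated RNA was bound to streptavidin beads from 6.5 ug of RNA, and input libraries were made from 300 ng of the same RNA. Input libraries had 11 and enriched libraries 15 cycles of PCR, and all were polyA-selected and sequenced as read pairs, per the labels' protocols.

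The authors deposited gene counts, which are whole numbers for 57992 Ensembl gene IDs in 40 libraries. The submitters' processing notes name HISAT2 2.1.0, SAMtools, HTSeq 0.7.2, deepTools 2.5.3 and DESeq2 and the build GRCh38/hg38. The annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. A second deposited table holds log2(TPM + 1) for the MITO groups, in which each column returned to a linear scale sums to 2000000, so that the authors added the TPM of both replicates. The authors also deposited 2 tables of log2 fold changes with a p-value per gene (unadjusted for ERM over NES, adjusted for LMNB1), which the submitters' processing notes assign to DESeq2. Those tables were compared with the results computed here and not used to make them. Symbols were taken from a table that paired 56948 of the IDs with a current symbol, and coordinates from the RefSeq annotation of GRCh38.p14.

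Libraries were grouped by title. The characteristics of 4 enriched ERM libraries and 4 LMNB1 libraries name s4U, while their titles and the series design name s6G, and the expression of ATF3 (given with the results) placed them with the s6G libraries. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersion shrinkage, TMM scaling, the default expression filter, Benjamini-Hochberg adjustment, called at an adjusted p of 0.05). The MITO libraries (16), the ERM and NES libraries (12) and the LMNB1 libraries (12) entered 3 separate fits of group means. This left 15151, 15619 and 16525 tested genes. Each arm's enriched libraries were compared with its inputs, differences between arms were tested as interaction terms, and inputs with a thionucleoside were compared with APEX-only inputs. Errors on log2 fold changes are standard errors from the fit, with n = 2 libraries per group (n = 4 for ERM). In the main fits the p-values measure the spread between libraries of a group, taken over all groups of a fit. They do not use the pairing of enriched and input libraries described below.

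A set of 35 gene lists (organelle and pathway genes, nuclear RNAs, stress and short-lived transcripts, and markers of other cell types) was fixed before the data were examined, as were the fits, the comparisons, the tests and the alternatives other than those stated as added. Lists of at least 5 tested members were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. For each list, members called over all genes are counted, and again with p adjusted over the list alone. Named genes followed a fixed rule. It took every tested mitochondrial mRNA and rRNA in the MITO fit and LMNB1 everywhere. It took up to 5 genes with the highest and 5 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 4 and no overlap between the compared groups. It also took up to 3 called members per list with the largest change in the direction of most called members. Genes outside the rule are said to be chosen after their values were seen.

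Enriched and input libraries of 1 number are the same biological replicate before and after enrichment, per the series design, so that number pairs them. Deviations from group means correlated between enriched and input libraries of 1 number with r = 0.72 (MITO s6G), 0.77 (MITO s4U), 0.59 (MITO APEX only), 0.19 (MITO unlabelled), 0.35 (NES), 0.70 (LMNB1 s6G), 0.58 (LMNB1 APEX only) and 0.10 (LMNB1 unlabelled), and 0.40, 0.29, 0.35 and 0.37 for ERM numbers 1 to 4. ERM numbers 1 and 3 correlated more with another number (0.47 and 0.43). The main fits had no block, and fits with the replicate number as a block were alternatives, printed with a result where they changed a call or moved a count by more than 1.5 times. Other alternatives were total-count and RLE scaling, TMM on nuclear genes, no filter, a filter at 10 counts, DESeq2 1.42.0, a fold threshold of 2, fits of the compared libraries alone, and leaving out each library. The fit was tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. For MITO s6G it recovered 5% and 78% of them (13291 genes, 3 false calls), for ERM 90% and 99% (15072 genes, 9 false calls), and for LMNB1 s6G 17% and 71% (15584 genes, 5 false calls). The simulated libraries were drawn independently, without the pairing of enriched and input libraries or the shift of mitochondrial RNA in the data. The recovered shares and false calls therefore need not hold for the real libraries.

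Library totals ranged from 123341 to 14496768 counts. Shares of a single library carry 95% Wilson intervals, and a group without counts was set to a floor of 3 counts over the group. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No value column was left unmapped, and no library was left out of the main fits. Results for 3 genes are not reported here.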

Results

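The series asked whether electron-rich nucleosides that living cells build into new RNA improve the capture of RNA close to a localised peroxidase. It holds 40 libraries in 18 groups, with 20 libraries of RNA bound to streptavidin and 20 of the RNA put in. The MITO construct was used in 4 arms (s6G, s4U, APEX only and unlabelled), LMNB1 in 3 (s6G, APEX only and unlabelled), and ERM and NES with s6G alone. Groups held 2 libraries, except for ERM with 4 enriched and 4 input libraries. Enriched MITO libraries held 3678046 to 4073107 counts with s6G, 3495198 to 5111763 with s4U, 2720817 to 6890758 in the APEX-only arm, and 123341 and 842177 without labelling. MITO inputs held 3514076 to 5725612 counts. ERM libraries held 5342584 to 14496768 counts, enriched NES libraries 7761433 and 8229934, and NES inputs 5415679 and 5647513. Enriched LMNB1 libraries held 7258396 and 8560346 counts with s6G, 6504472 and 6216616 in the APEX-only arm, and 1492243 and 3876715 without labelling, and LMNB1 inputs held 3913738 to 6132219.

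Levels of LMNB1 and SEC61B set apart the libraries of 2 constructs. LMNB1 (ENSG00000113368, chromosome 5, 126776623 to 126837020), which encodes lamin B1 of the nuclear lamina, had 2340 to 6730 CPM in the 12 libraries of the LMNB1 construct and 77.8 to 340 CPM in the 28 others. The lowest of the former was 6.88 times the highest of the latter. LMNB1 levels also differed by arm before enrichment. In inputs of its construct the mean was 4570 ± 681 CPM with s6G, 2600 ± 368 in the APEX-only arm and 2850 ± 495 without labelling (SD, n = 2). In MITO inputs it went the other way, at 158 ± 6.95, 289 ± 72.6 and 276 ± 26.7 CPM. The cause was not tested. LMNB1 itself was not called between enriched and input libraries of its construct (log2 fold change 0.25 ± 0.21 with s6G, edgeR adjusted p = 0.47, n = 2). SEC61B (chromosome 9, 99222282 to 99230615), a subunit of the channel that moves proteins into the endoplasmic reticulum, had 1090 to 1260 CPM in ERM inputs and 2700 to 3450 CPM in enriched ERM libraries, against 57.1 to 235 CPM in the 32 other libraries. ATF3, a stress-induced transcription factor chosen after its values were seen, had 166 to 190 CPM in the LMNB1 inputs titled s6G and 248 to 268 CPM in MITO s6G inputs, against 37 to 54.2 CPM in MITO s4U inputs. In enriched libraries it had 935 to 1030 CPM for ERM, 224 to 249 CPM for LMNB1 titled s6G and 280 to 337 CPM for MITO s6G, against 49.5 to 85.1 CPM for MITO s4U.

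**Figure D1:**
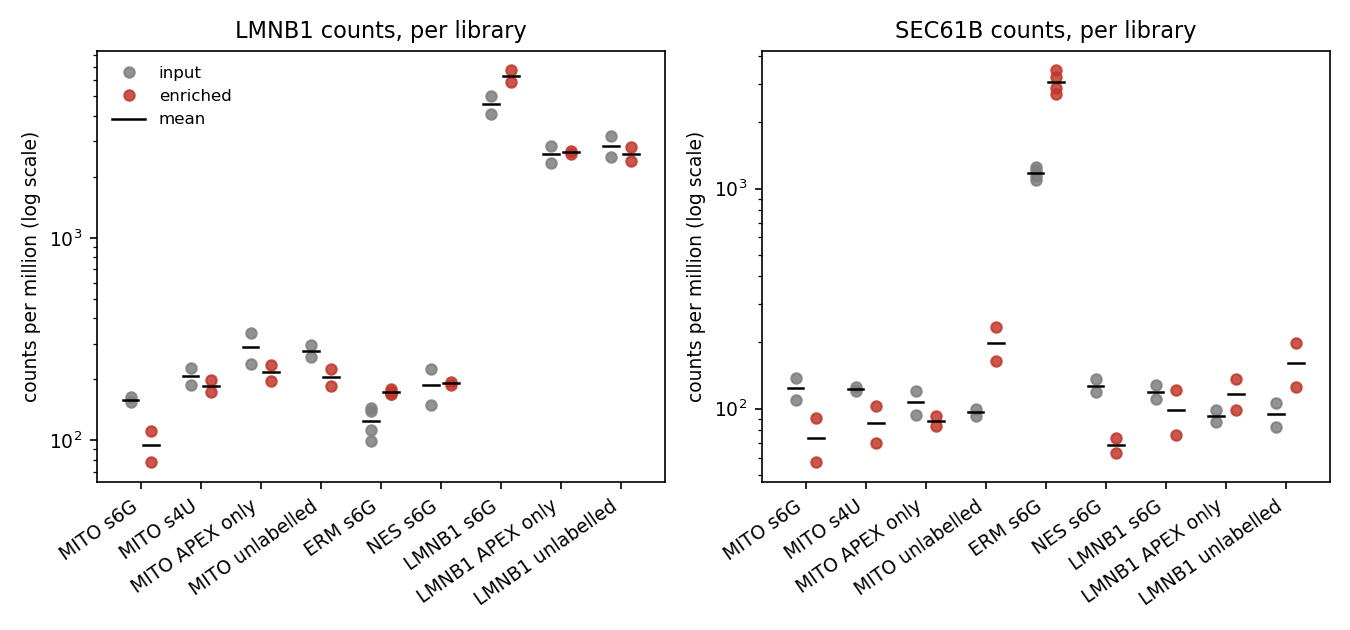
CPM of LMNB1 and SEC61B in each of the 40 libraries, on a log axis, by construct and library type. LMNB1 lies between 2340 and 6730 CPM in LMNB1-construct libraries and at most at 340 elsewhere, and SEC61B lies at 1090 CPM or above in ERM libraries and at most at 235 elsewhere.

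RNA encoded by mitochondrial DNA, which is made and kept in the mitochondrial matrix, took up a larger part of the enriched MITO libraries of all 3 labelled arms. Its share of counts was 47.2% ± 15.7 (SD, n = 2) after enrichment and 5.72% ± 0.255 in the inputs with s6G, 32.6% ± 8.85 and 4.18% ± 0.112 with s4U, and 37% ± 3.98 and 4.12% ± 0.782 in the APEX-only arm. In the unlabelled arm the shares were 6.81% ± 3.85 and 5.14% ± 0.47. The single enriched libraries held 36.1% (95% Wilson interval 36 to 36.1) and 58.2% (58.2 to 58.3) with s6G, 26.3% (26.3 to 26.4) and 38.8% (38.8 to 38.9) with s4U, and 39.8% (39.8 to 39.9) and 34.2% (34.2 to 34.2) in the APEX-only arm. Those of the unlabelled arm held 4.09% (3.98 to 4.2) and 9.53% (9.47 to 9.59). With the ERM and NES constructs the share was lower after enrichment, at 1.78% ± 0.265 against 7.47% ± 0.478 for ERM (n = 4) and 1.82% ± 0.0291 against 6.52% ± 0.387 for NES (n = 2). For LMNB1 it was 1.92% ± 0.373 against 5.25% ± 1.59 with s6G, 3.45% ± 0.759 against 3.92% ± 0.641 in the APEX-only arm and 5.93% ± 0.638 against 3.79% ± 0.694 without labelling. In an exact two-sided permutation test the ERM difference of -5.69 points had p = 0.0286, the smallest possible with 4 against 4. Swapping enriched and input libraries only within the 4 pairs, an exact two-sided permutation test added after the data were seen, gave p = 0.125, the smallest that 4 pairs allow, so the call under 0.05 is lost with the pairing. Each MITO difference of the labelled arms (41.4, 28.4 and 32.9 points) had an exact p = 0.333, the smallest that 2 against 2 libraries can give, and 0.5 within the 2 pairs.

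**Figure D2:**
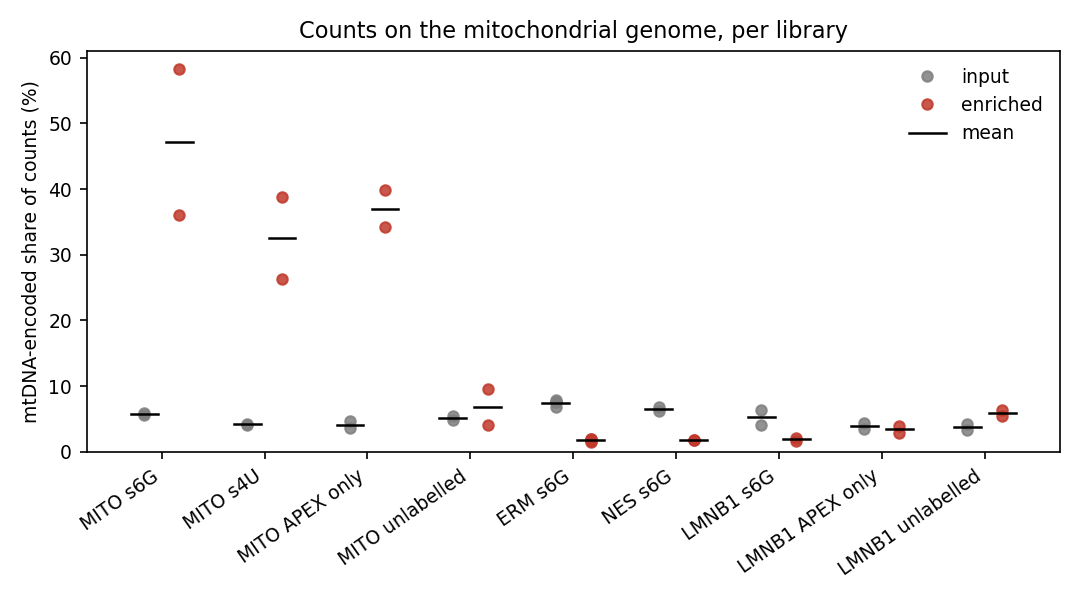
Share of counts (%) from mitochondrial DNA in each library, inputs in grey and enriched libraries in red, with group means as bars. Enriched MITO libraries of the labelled arms lie between 26.3% and 58.2%, and those of the unlabelled arm at 4.09% and 9.53%.

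With s6G, mitochondrial transcripts led the genes enriched by the MITO construct, over 10-fold for most. All 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and the ATP synthase, rose, with a median log2 fold change of 3.86. Examples are MT-CO1 of complex IV (4.28 ± 0.54, edgeR adjusted p = 0.000843, n = 2), MT-ND2 of complex I (4.26 ± 0.53) and MT-ND6, the mRNA encoded on the light strand (4.13 ± 0.40, adjusted p = 0.000238). The weakest were MT-ND4L (3.20 ± 0.63) and MT-ATP8 (3.14 ± 0.49). Both mitochondrial rRNAs rose, MT-RNR2 by 4.75 ± 0.63 and MT-RNR1 by 4.00 ± 0.49, as did 2 of 4 tested mitochondrial tRNAs (MT-TP 4.19 ± 0.46, and MT-TC at least 20.1-fold higher). MTCO1P12 (4.55 ± 0.55) is a nuclear copy of MT-CO1 whose reads cannot be told from it. Outside the mitochondrial genome, the immediate-early gene FOS rose by 4.70 ± 0.94 (adjusted p = 0.0496) and FOSB by 3.32 ± 0.66. In the edgeR fit without a block 4 genes fell: RN7SL2, an RNA of the signal recognition particle with near-identical copies (-4.02 ± 0.56), SELENON, WNK2 and FOCAD.

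In the edgeR test this gave 44 higher and 4 lower of 15151 genes, and 17 of the 44 were encoded by mitochondrial DNA, out of 19 tested. A fit of only the compared libraries called 0, and DESeq2 341 higher and 261 lower. The mRNAs stood apart as a list (13 of 13 adjusted over the list alone, camera adjusted p = 1.72e-76, and 0.352 with an estimated correlation and the replicate block), as did immediate-early genes (2 of 39 higher, 3 adjusted over the list alone, median 0.88 with TMM and -0.04 with total counts, adjusted p = 3.06e-12, and adjusted p = 0.0682 with an estimated correlation). Lysosomal genes lay lower (0 of 26 called, 1 higher and 5 lower adjusted over the list alone, median -0.39, adjusted p = 0.000115, and 0.199 with an estimated correlation and the replicate block), as did secreted and matrix proteins (0 of 29 called, 1 lower adjusted over the list alone, median -0.72, adjusted p = 1.76e-09, and adjusted p = 0.312 with an estimated correlation). With the replicate number as a block, edgeR called 526 higher and 507 lower, including 14 higher immediate-early genes, 12 lower genes of secreted proteins, and 6 lower and 1 higher lysosomal genes. The count was 17 without enriched library 2 and 13 without either input. Scaling sets the split: 91.7% of calls were higher with TMM and 1.35% with total counts, which moved the median of all genes by -0.87.

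The s4U arm asked the same of another thionucleoside, with 12 of 13 mitochondrial mRNAs higher (13 adjusted over the list alone, median 3.20, camera adjusted p = 8.3e-75, and 0.315 with an estimated correlation and the replicate block). MT-CO1 rose by 3.81 ± 0.52 (edgeR adjusted p = 0.00422, n = 2), MT-CO3 of complex IV by 3.55 ± 0.50 and MT-RNR1, the small rRNA of mitochondrial ribosomes, by 3.66 ± 0.48. MT-ND4L, at 3.04 ± 0.63, missed the threshold (adjusted p = 0.115). Beyond these, MT-RNR2 (3.49 ± 0.59), MT-TP (3.59 ± 0.45) and MTCO1P12 (4.39 ± 0.55) rose. Secreted and matrix proteins lay lower (0 of 29 called, 13 lower adjusted over the list alone, median -1, adjusted p = 2.53e-20, and adjusted p = 0.0844 with an estimated correlation), and so did lysosomal genes (0 of 26 called, 2 lower adjusted over the list alone, median -0.44, adjusted p = 8.62e-07, and 0.0846 with an estimated correlation and the replicate block). In all, edgeR called 17 genes higher and 0 lower (1050 genes at an unadjusted p under 0.05, and 140 higher and 247 lower by DESeq2), and 15 of the 17 were mitochondrial. With the replicate number as a block, 266 rose and 489 fell, the latter with 18 genes of secreted proteins and 4 lysosomal genes. No gene was called without either input (0 and 0). With total counts, 14.4% of calls were higher instead of 100%, and the median of all genes moved by -0.45.

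Without a thionucleoside, APEX labelling alone also enriched mitochondrial transcripts in the matrix. Again 12 of 13 mRNAs rose (13 adjusted over the list alone, median 3.05, camera adjusted p = 3.52e-65, and 0.353 with an estimated correlation and the replicate block), led by MT-CO1 (5.26 ± 0.56, edgeR adjusted p = 0.00029, n = 2), MT-ND6 (4.30 ± 0.41, adjusted p = 0.000149) and MT-ND5 of complex I (3.87 ± 0.45). MT-ND4L lay at 2.90 ± 0.62 (adjusted p = 0.0788). MT-RNR2 rose by 3.31 ± 0.59 and MT-RNR1 by 3.02 ± 0.47. Among nuclear transcripts, SNHG12, a host of small nucleolar RNAs, rose by 1.59 ± 0.31, and hosts of this kind stood higher as a list (1 of 20, 10 adjusted over the list alone, median 0.87, adjusted p = 7.55e-09, and adjusted p = 0.0707 with an estimated correlation). So did genes with detained introns (0 of 35 called, 7 adjusted over the list alone, median 0.58 with TMM and -0.15 with total counts, adjusted p = 1.4e-08, and adjusted p = 0.569 with an estimated correlation). RN7SL2 fell by 5.43 ± 0.61 on the log2 scale, TMTC3 by 1.5 ± 0.28 and LRP3 by 1.40 ± 0.27. The edgeR count was 38 higher and 3 lower, 16 of them mitochondrial (DESeq2 421 and 179, and 75 in all in a fit of only the compared libraries), and with the replicate number as a block 656 and 427, with 11 hosts of small nucleolar RNAs and 16 genes with detained introns among the higher. It was 23 and 12 without enriched libraries 1 and 2, and 6 and 5 without inputs 1 and 2. Total counts turned the higher share from 92.7% to 2.65% and moved the median of all genes by -0.73.

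**Figure D3:**
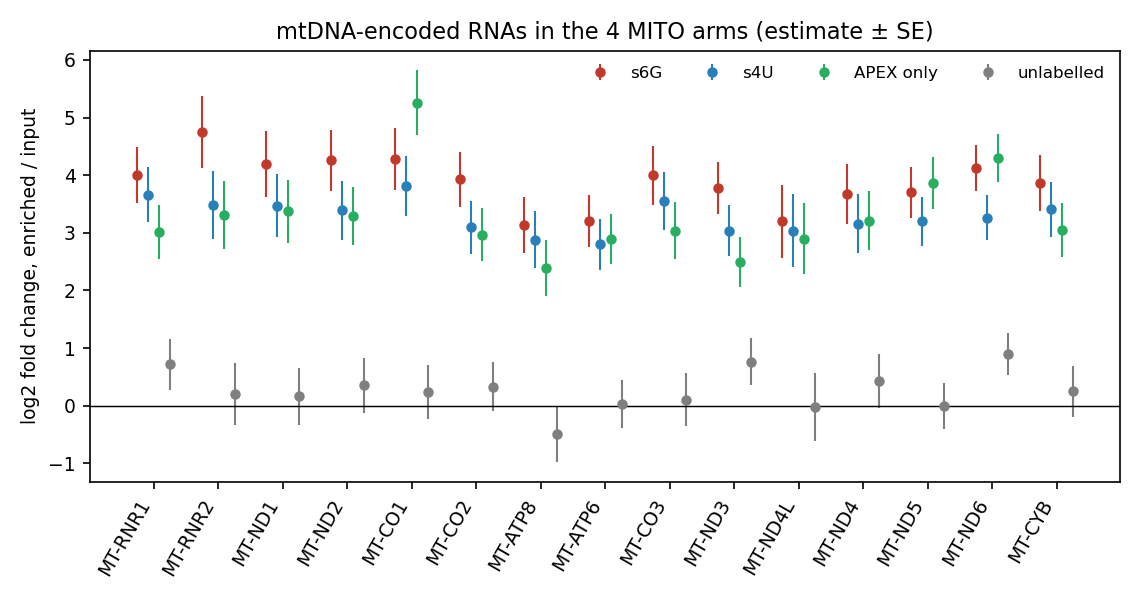
Log2 fold change of 15 mitochondrial RNAs (13 mRNAs and 2 rRNAs) between enriched and input MITO libraries in 4 arms, with standard errors. In the labelled arms the values lie between 2.39 (MT-ATP8, APEX only) and 5.26 (MT-CO1, APEX only), and in the unlabelled arm between -0.50 (MT-ATP8) and 0.90 (MT-ND6).

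The unlabelled MITO arm measured what the beads held without biotin, and none of the 13 mitochondrial mRNAs or 2 rRNAs passed the test there, though 2 of the mRNAs were called higher with the replicate block (0 adjusted over the list alone). MT-CO1 lay at 0.23 ± 0.47 (edgeR adjusted p = 0.79, n = 2) and MT-RNR2 at 0.20 ± 0.54. Among abundant RNAs, KCNQ1OT1, a long nuclear RNA, rose by 2.64 ± 0.51 (adjusted p = 0.0107), RPS29, a ribosomal protein gene, by 1.96 ± 0.33, and the splicing factor gene U2AF1, which has a near-identical copy, by 2.43 ± 0.34. BARX1 was at least 7.61-fold lower. Enzymes of nucleotide synthesis fell in 5 of 28 cases (PPAT -2.40 ± 0.47, CAD -1.30 ± 0.31, GART -1.20 ± 0.30; 9 adjusted over the list alone, camera adjusted p = 0.00079, and adjusted p = 0.524 with an estimated correlation). In total 876 genes rose and 620 fell, with 1 mitochondrial RNA among them (MT-TF 5.81 ± 1.62). This arm holds the 2 shallowest libraries. The count was 1723 and 1716 without enriched library 1 or 2 and 0 without either input (4147 at an unadjusted p under 0.05 with all libraries; DESeq2 called 1519 and 583). The stricter filter left 302 and a fit of only the compared libraries 320. The replicate block gave 1499 and 1606, with 11 lower genes of nucleotide synthesis. The share of higher calls was 58.6%, against 84.6% with total counts (median of all genes moved by 0.20) and 75.2% with RLE scaling (0.22).

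Differences between the labelled MITO arms ask whether a thionucleoside adds to APEX labelling. For mitochondrial RNAs none passed the test, which does not show that the arms enrich them alike. In simulated counts of MITO s6G enriched and input libraries, the fit recovered 5% of 2-fold and 78% of 4-fold changes. Between s6G and APEX only, MT-ND3 of complex I differed by 1.28 ± 0.58, MT-RNR2 by 1.44 ± 0.76 and MT-CO1 by -0.98 ± 0.66 (edgeR adjusted p = 1 for each, n = 2). Between s4U and APEX only, MT-CO1 differed by -1.45 ± 0.67 and MT-ND6 by -1.04 ± 0.50 (adjusted p = 1). In these comparisons edgeR called 0 genes (371 and 415 at an unadjusted p under 0.05), DESeq2 13 and 3, and edgeR with the replicate block 9 and 17. Chosen after their values were seen, the 9 include NUDT19 (1.97 ± 0.40 with the block, adjusted p = 0.0195) and CDC42EP4 (1.96 ± 0.38), and the 17 include MDM2, a p53 target and ubiquitin ligase of p53 (1.68 ± 0.35, adjusted p = 0.014), and PAFAH1B2 (1.76 ± 0.33). As a list, immediate-early genes lay higher with s6G than in the APEX-only arm (0 of 39 called, 0 adjusted over the list alone, median 0.76, camera adjusted p = 3.77e-10, and adjusted p = 0.108 with an estimated correlation), with 1 called and 7 adjusted over the list alone under the block. Cytosolic ribosomal proteins lay lower with s4U (0 called, 0 adjusted over the list alone, median -0.71, adjusted p = 8.38e-22, and adjusted p = 0.204 with an estimated correlation).

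The purine s6G and the pyrimidine s4U were given at the same dose and for the same time, and their readouts can be set side by side. MT-RNR2 differed by 1.26 ± 0.76 between them (95% interval -0.35 to 2.88), MT-ND6 by 0.87 ± 0.50 (-0.20 to 1.93) and MT-CO1 by 0.47 ± 0.66 (-0.93 to 1.87), each with an edgeR adjusted p = 1 (n = 2). The 13 mRNAs had a median difference of 0.50 with TMM and of -0.03 with total counts, which moved the median of all genes by -0.42 (camera adjusted p = 0.00317 with TMM, 0.0997 with the replicate block, and adjusted p = 0.999 with an estimated correlation). No gene was called by edgeR (0, with 88 at an unadjusted p under 0.05) or DESeq2 (0), or with the replicate block (0, with 341 at an unadjusted p under 0.05). A missed threshold does not show that both nucleosides act alike, and the intervals leave room for a 2-fold difference of MT-RNR2 or MT-CO1.

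Set against the unlabelled arm, the enrichment of mitochondrial RNA stayed larger in each labelled arm. With s6G, MT-RNR2 differed by 4.55 ± 0.80 (edgeR adjusted p = 0.0341, n = 2), MT-CO1 by 4.04 ± 0.69, MT-ND1 of complex I by 4.04 ± 0.73 and MT-RNR1 by 3.29 ± 0.63, with 11 of 13 mRNAs higher (13 adjusted over the list alone, median 3.61, camera adjusted p = 1.42e-29, and adjusted p = 0.176 with an estimated correlation). With s4U, 5 mRNAs were higher, among them MT-CO1 (3.58 ± 0.68, adjusted p = 0.0459) and MT-CO3 (3.45 ± 0.66) (13 adjusted over the list alone, median 3.06, adjusted p = 9.96e-23, and adjusted p = 0.338 with an estimated correlation). In the APEX-only arm, 3 were higher, namely MT-CO1 (5.03 ± 0.70, adjusted p = 0.0238), MT-ND5 (3.89 ± 0.58) and MT-ND6 (3.40 ± 0.52) (13 adjusted over the list alone, median 2.91, adjusted p = 6.76e-27, and adjusted p = 0.214 with an estimated correlation). The replicate block called 12 of 13 in each. RN7SL2 was lower with s6G (-3.84 ± 0.79) and in the APEX-only arm (-5.25 ± 0.83).

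Over all genes, edgeR called 42 higher and 15 lower for s6G, 29 and 11 for s4U, and 5 and 1 for APEX only, and 1048 and 525, 1046 and 562, and 738 and 317 with the replicate block. For s6G, RLE scaling left 21, the stricter filter 23 and a fit of only the compared libraries 0, and for s4U each of the 3 left 0. DESeq2 called 694, 753 and 456. The counts also rest on single libraries. For s6G, the count was 33 without enriched s6G library 1, 167 and 859 without enriched unlabelled libraries 1 and 2, 21 without unlabelled input 2, and 0 without enriched s6G library 2 or any of the 3 other inputs. For s4U, it was 65 without enriched s4U library 2, 153 and 831 without enriched unlabelled libraries 1 and 2, and 0 without enriched s4U library 1 or any of the 4 inputs. For APEX only, it was 4 without enriched library 1, 11 and 901 without enriched unlabelled libraries 1 and 2, 2 without unlabelled input 1, and 0 without enriched library 2 or either APEX-only input. Total counts turned the higher share from 73.7% to 2.97%, from 72.5% to 16.9% and from 83.3% to 50%, and moved the median of all genes by -1.09, -0.67 and -0.94 (RLE scaling by -0.17, -0.19 and -0.19).

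The MITO inputs show what a thionucleoside did to the RNA of whole cells. With s6G, RBM15, an RNA-binding protein of the m6A methylation machinery, rose by 2.02 ± 0.30 (edgeR adjusted p = 0.0196, n = 2) and COL7A1, a collagen gene, by 1.96 ± 0.32, both over APEX-only inputs. Replication-dependent histone genes lay higher as a list (0 of 18 called, 10 adjusted over the list alone, median 2.15, camera adjusted p = 7.25e-13, and adjusted p = 0.0704 with an estimated correlation), and so did cytosolic ribosomal proteins (0 called, 0 adjusted over the list alone, median 0.62, adjusted p = 2.56e-19, and adjusted p = 0.428 with an estimated correlation). Most histone mRNAs end without a polyA tail, and their close copies share reads. In this fit no mitochondrial mRNA was called, with MT-CO1 at 0.78 ± 0.47 (adjusted p = 0.703). With s6G, 8 genes rose and 0 fell (DESeq2 88 and 92). The replicate block left 0, total counts 0 and moved the median of all genes by -0.17, and leaving out any of the 4 libraries left 1 (s6G input 2) or 0 (each of the others). The block assumes that numbers match between arms, but deviations of number 1 correlated at -0.49 between s6G and APEX-only inputs. Crossing the APEX-only numbers raised the s6G count, as given with the alternatives. With s4U, edgeR called 0 genes (583 at an unadjusted p under 0.05, DESeq2 9 higher and 44 lower), with ribosomal proteins higher as a list (0 called, 0 adjusted over the list alone, median 0.47, adjusted p = 4.45e-17, and adjusted p = 0.964 with an estimated correlation).

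At the ER membrane with s6G, histone, zinc finger and immediate-early transcripts rose after enrichment, and mitochondrial and housekeeping transcripts fell. H1-4, a linker histone gene, rose by 6.59 ± 0.42 (edgeR adjusted p = 5.59e-08, n = 4), and 21 of 24 replication-dependent histone genes rose in all (22 adjusted over the list alone, median 2.42, camera adjusted p = 8.11e-08, and adjusted p = 0.196 with an estimated correlation). KRAB zinc finger repressors rose in 42 of 49 cases (42 adjusted over the list alone, median 1.16, adjusted p = 6.6e-10, and 0.196 with an estimated correlation), such as ZNF460 (2.81 ± 0.23) and ZNF264 (2.01 ± 0.13), and immediate-early genes in 28 of 38 (29 adjusted over the list alone, median 1.11, adjusted p = 4.11e-06, and 0.204 with an estimated correlation), such as CCN2 (2.73 ± 0.60) and IER5 (1.80 ± 0.16). All 13 mitochondrial mRNAs fell (13 adjusted over the list alone, median -2.64, adjusted p = 4.2e-20, and 0.112 with an estimated correlation), MT-CO1 by 3.05 ± 0.15 on the log2 scale. So did all 49 cytosolic ribosomal protein genes (49 adjusted over the list alone, median -1.63, adjusted p = 4e-26, and 0.196 with an estimated correlation), 20 of 21 glycolytic genes (20 adjusted over the list alone, median -1.56, adjusted p = 1.13e-12, and 0.196 with an estimated correlation), such as GAPDH (-2.08 ± 0.17) and ALDOA (-2.06 ± 0.11), and 37 of 40 nuclear genes of the respiratory chain (37 adjusted over the list alone, median -1.40, adjusted p = 4.74e-15, and 0.196 with an estimated correlation).

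Transcripts of proteins made at the ER went both ways in these libraries. Membrane transporters rose in 21 and fell in 6 of 30 cases (median 0.73, camera adjusted p = 0.00409, and adjusted p = 0.196 with an estimated correlation), with SLC30A1, a zinc exporter (2.49 ± 0.19, edgeR adjusted p = 5.82e-09, n = 4), and ATP1B1 of the sodium pump (1.83 ± 0.14) among them. Golgi enzymes rose in 14 and fell in 4 of 24 (median 0.77, adjusted p = 0.0126, and 0.196 with an estimated correlation), led by MGAT2 (2.87 ± 0.49) and CHSY1 (2.40 ± 0.13). Secreted and matrix proteins fell in 25 of 29 (median -1.40, adjusted p = 9.11e-12, and 0.0635 with an estimated correlation), with TIMP1, an inhibitor of metalloproteases, at -2.34 ± 0.12 and HSPG2 at -1.90 ± 0.24. For these 3 lists the counts adjusted over the list alone were the same. Of 15619 genes, edgeR called 5362 higher and 4508 lower, and 2791 and 2468 beyond a 2-fold change. Total counts moved the higher share from 54.3% to 67.9% and the median of all genes by 0.31. MIR3648-1 (5.46 ± 1.27) lies inside the ribosomal RNA gene RNA45SN2, whose reads it shares.

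In the cytosol with s6G, transcripts of immediate-early genes and short-lived transcription factors rose after enrichment, and those of secreted, lysosomal and translocon proteins fell. H1-4 rose by 5.95 ± 0.65 (edgeR adjusted p = 1.07e-05, n = 2) and H4C1 was at least 7.84-fold higher. Immediate-early genes rose in 31 of 38 cases (32 adjusted over the list alone, median 1.86, camera adjusted p = 7.89e-13, and adjusted p = 0.133 with an estimated correlation), such as DUSP5, a MAP kinase phosphatase (3.34 ± 0.60), and JUN (2.76 ± 0.26). Short-lived transcription factors rose in 31 of 37 (31 adjusted over the list alone, median 1.76, adjusted p = 3.56e-13, and adjusted p = 0.104 with an estimated correlation), such as SOX4 (2.65 ± 0.22). Secreted and matrix proteins fell in 26 of 29 (27 adjusted over the list alone, median -1.68, adjusted p = 6.57e-15, and 0.0899 with an estimated correlation and the replicate block), such as LAMA5, a laminin (-2.33 ± 0.28), and PLOD3 (-2.32 ± 0.21). Lysosomal genes fell in 22 of 26 (22 adjusted over the list alone, median -1.03, adjusted p = 4.36e-08, and adjusted p = 0.12 with an estimated correlation), such as the protease gene TPP1 (-2.17 ± 0.18), and translocon genes in 18 of 27 (18 adjusted over the list alone, median -0.89, adjusted p = 2.21e-05, and adjusted p = 0.41 with an estimated correlation), such as STT3B of the oligosaccharyltransferase (-1.53 ± 0.14). Membrane transporters stood at a median of -0.03, with 12 higher and 9 lower of 30 (12 and 10 adjusted over the list alone, adjusted p = 0.771). MT-RNR2 fell by 2.89 ± 0.24 on the log2 scale. Of all genes, 4486 rose and 4126 fell. ERM and NES shared 4080 higher genes (1540 by independence) and 3463 lower genes (1190), with 13 in opposite directions.

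Transporter transcripts were enriched more with ERM than with NES (0 of 30 called over all genes, 16 adjusted over the list alone, median difference 0.57, camera adjusted p = 1.73e-15), a call that held with an estimated correlation (0.0122) and with the replicate block as well (0.0333). Surface receptors (0 of 34 called, 10 adjusted over the list alone, median 0.53, adjusted p = 1.05e-11) had an adjusted p = 0.0596 with an estimated correlation and 0.0225 with the block added. Golgi enzymes (0 called, 7 adjusted over the list alone, median 0.35, adjusted p = 4.1e-06) had 0.0596 and 0.0493. Secreted and matrix proteins (0 of 29 called, 7 adjusted over the list alone, median 0.47, adjusted p = 2.43e-07) and lysosomal genes (0 of 26 called, 4 adjusted over the list alone, median 0.40, adjusted p = 1.37e-09) each had an adjusted p = 0.0596 with an estimated correlation. Immediate-early genes were enriched less (0 of 38 called, 23 adjusted over the list alone, median -0.83, adjusted p = 1.45e-16, and adjusted p = 0.0596 with an estimated correlation). With the block, 17 transporters, 12 surface receptors, 8 secreted proteins, 7 lysosomal genes and 6 Golgi enzymes were called higher and 18 immediate-early genes lower.

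Of single genes, only SEC61B differed in the edgeR fit (2.04 ± 0.23, 95% interval 1.55 to 2.54, adjusted p = 0.00102, n = 4 and 2), with 1 gene higher and 0 lower (2167 at an unadjusted p under 0.05, DESeq2 105 and 358). With the replicate block 393 genes were higher and 559 lower. Chosen after their values were seen, the higher include HSPA5, a chaperone of the ER (0.86 ± 0.13 with the block, adjusted p = 0.002), MAN1A1, a Golgi mannosidase (1.22 ± 0.17, adjusted p = 0.00163), and the inositol carrier SLC5A3 (1.39 ± 0.23, adjusted p = 0.00386). The lower include EGR1 (-1.61 ± 0.22, adjusted p = 0.00131) and JUN (-0.98 ± 0.15, adjusted p = 0.00239), both immediate-early genes. The count was 0 without enriched NES library 1 or NES input 2, 2 without enriched ERM library 2 and 9 without enriched ERM library 4. ERM numbers 3 and 4 were deeper (12382757 to 14496768 counts) than 1 and 2 (5342584 to 6664875). Alone against NES, numbers 3 and 4 gave 624 higher and 858 lower, and numbers 1 and 2 gave 347 and 431. The authors' deposited table of ERM over NES correlated with the log2 fold changes of enriched ERM over enriched NES libraries at r = 1 across genes, which are not independent replicates, and with the difference of enrichments at r = 0.63. Enriched libraries alone gave 511 higher and 424 lower genes, and inputs alone 44 and 93.

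**Figure D4:**
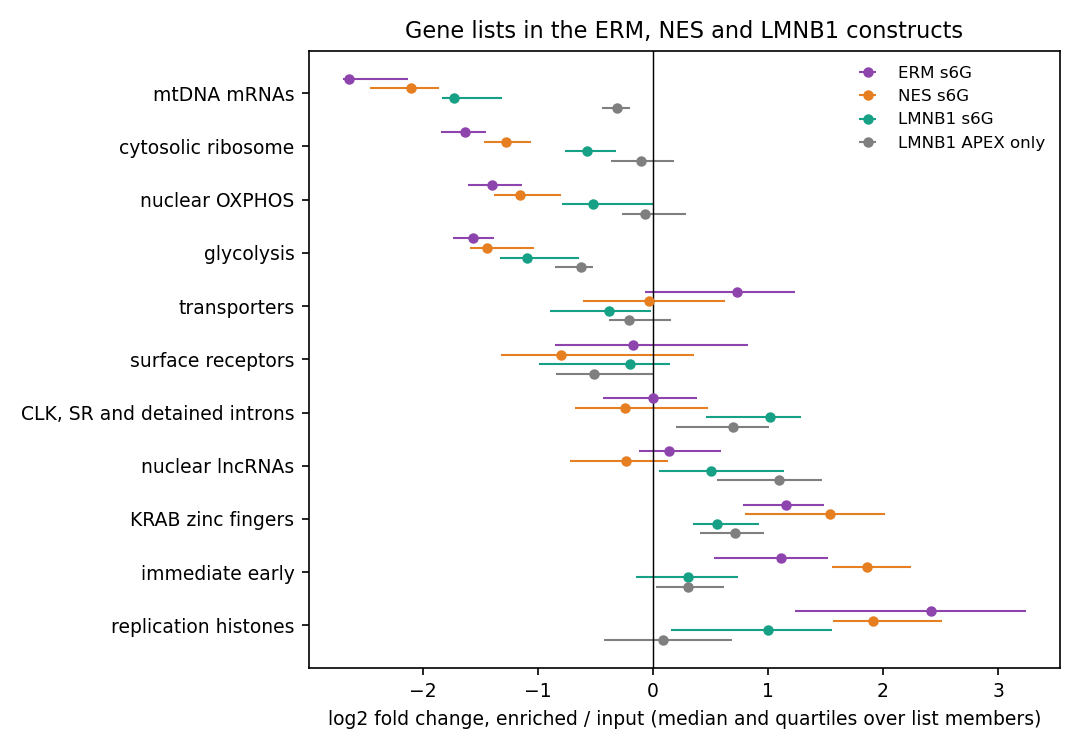
Median log2 fold change between enriched and input libraries of 11 gene lists, with quartiles, for ERM, NES and LMNB1 with s6G and for LMNB1 APEX only. Mitochondrial mRNAs lie at -2.64 for ERM, -1.73 for LMNB1 with s6G and -0.31 for LMNB1 APEX only, and immediate-early genes at 1.11 for ERM and 1.86 for NES.

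At the nuclear lamina with s6G, transcripts with detained introns rose, and glycolytic, cytoskeletal and mitochondrial transcripts fell. Genes with detained introns, many of which encode splicing regulators, rose in 19 of 36 cases (20 adjusted over the list alone, median 1.02, camera adjusted p = 9.58e-13, and adjusted p = 0.176 with an estimated correlation), such as RBM5 (1.91 ± 0.33, edgeR adjusted p = 0.00301, n = 2) and NKTR (1.80 ± 0.24). Among nuclear long RNAs MIR17HG (1.95 ± 0.45), MALAT1 (1.52 ± 0.42), a component of nuclear speckles, and TUG1 (1.5 ± 0.21) rose (3 of 21, 3 adjusted over the list alone, median 0.51, adjusted p = 0.0318, and adjusted p = 0.156 with an estimated correlation). Hosts of small nucleolar RNAs rose in 9 of 20 cases and fell in 1 (11 and 2 adjusted over the list alone, median 0.85, adjusted p = 0.000358, and adjusted p = 0.346 with an estimated correlation). RANBP6, an importin, rose by 2.36 ± 0.24 (adjusted p = 0.000359), and KDELR1, which returns proteins to the ER, fell by 2.36 ± 0.18 on the log2 scale. Mitochondrial mRNAs fell in 11 of 13 cases (12 adjusted over the list alone, median -1.73, adjusted p = 1.24e-17, and adjusted p = 0.099 with an estimated correlation), glycolytic genes in 14 of 21 (14 adjusted over the list alone, median -1.09, adjusted p = 1.33e-15, and adjusted p = 0.0598 with an estimated correlation) and cytoskeletal genes in 16 of 27 (18 adjusted over the list alone, median -0.99, adjusted p = 1.6e-17, and adjusted p = 0.0598 with an estimated correlation), such as ACTB (-2.20 ± 0.35).

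Nuclear envelope proteins themselves stood at a median of 0.01, with 3 of 20 transcripts higher and 4 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.17), EMD, which encodes emerin, among the latter (-1.16 ± 0.20, edgeR adjusted p = 0.00315, n = 2). Secreted and matrix proteins fell in 18 of 30 cases and rose in 1 (19 and 1 adjusted over the list alone, median -1.30, adjusted p = 2.6e-14, and adjusted p = 0.141 with an estimated correlation). In all, 887 genes rose and 1263 fell of 16525, and 1380 and 1746 with the replicate block, with 2 hosts of small nucleolar RNAs among the lower. The count was 1176, 805, 984 and 784 without enriched libraries 1 and 2 and inputs 1 and 2, and 3660 in a fit without the shallowest unlabelled library. Total counts moved the higher share from 41.3% to 63.7% and the median of all genes by 0.21.

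For APEX labelling alone at the lamina fewer genes were called than with s6G, though the edgeR test between these arms called 0 genes in the main fit and with the replicate block. That count depends on the setting. DESeq2, total counts, a fit of only the compared libraries and a fit without the shallowest unlabelled library each called some, as given with the alternatives. MIR17HG, the host of a microRNA cluster, rose by 2.14 ± 0.45 (edgeR adjusted p = 0.0423, n = 2), CCNL1, a cyclin with a detained intron, by 1.51 ± 0.21 (adjusted p = 0.023), NKTR by 1.34 ± 0.24 and GAS5, a host of small nucleolar RNAs, by 1.30 ± 0.25. Nuclear long RNAs lay higher as a list (1 of 21, 8 adjusted over the list alone, median 1.10, camera adjusted p = 5.42e-07, and 0.272 with an estimated correlation and the replicate block), as did genes with detained introns (6 of 36, 15 higher and 1 lower adjusted over the list alone, median 0.70, adjusted p = 5.71e-11, and adjusted p = 0.313 with an estimated correlation). Glycolytic genes fell in 4 of 21 cases (12 adjusted over the list alone, median -0.62, adjusted p = 1.36e-10, and adjusted p = 0.148 with an estimated correlation), such as ALDOA (-1.20 ± 0.19, adjusted p = 0.023). EMD fell by 1.04 ± 0.20 on the log2 scale and EEF2, a factor of translation elongation, by 1.28 ± 0.23. Here 68 genes rose and 169 fell (DESeq2 343 and 708, and 1317 in all in a fit of only the compared libraries), and with the replicate block 196 and 478, with 5 nuclear long RNAs and 10 genes with detained introns among the higher and 8 glycolytic genes among the lower. Leaving out any of the 4 libraries of this arm ended every call (0 each). RLE scaling gave 55 and 90 and the fit without the shallowest unlabelled library 992 in all. Total counts turned the higher share from 28.7% to 65.9% and moved the median of all genes by 0.14. With s6G and with APEX only, 55 genes were higher in both (3.65 by independence) and 121 lower (12.9).

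The unlabelled LMNB1 arm gave few calls. FAM98B rose by 2.80 ± 0.37 (edgeR adjusted p = 0.0325, n = 2). HASPIN, a mitotic histone kinase, fell by 2.29 ± 0.34 on the log2 scale. Cytosolic ribosomal proteins lay higher (0 of 49 called, 19 adjusted over the list alone, median 0.60, camera adjusted p = 9.93e-13, and adjusted p = 0.535 with an estimated correlation). Transporters lay lower (1 of 30 called, 3 adjusted over the list alone, median -0.49, adjusted p = 2.25e-07, and 0.417 with an estimated correlation and the replicate block), the called member being the acetyl-CoA carrier SLC33A1 (-1.64 ± 0.25). The edgeR test called 4 higher and 2 lower (2866 at an unadjusted p under 0.05, DESeq2 436), and a fit of only the compared libraries 0. The count was 1064 and 639 without enriched libraries 1 and 2 and 0 without either input. Other settings gave 2 higher and 0 lower (RLE scaling), 4 and 6 (TMM on nuclear genes) and 5 and 0 (replicate block, with 0 transporters called and 10 adjusted over the list alone).

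Differences between the LMNB1 arms ask what s6G added. Against the unlabelled arm, mitochondrial mRNAs were enriched less with s6G in 10 of 13 cases (13 adjusted over the list alone, median -2.14, camera adjusted p = 3.85e-27, and adjusted p = 0.184 with an estimated correlation), such as MT-CO1 (-2.64 ± 0.46, edgeR adjusted p = 0.0184, n = 2) and MT-ND3 (-2.46 ± 0.30). Genes with detained introns were enriched more in 4 of 36 (14 adjusted over the list alone, 8 over all genes with the replicate block, median 0.80, adjusted p = 1.77e-07, and adjusted p = 0.444 with an estimated correlation), such as NKTR (1.72 ± 0.34), as were TUG1 (1.84 ± 0.31) and RBM15 (2.14 ± 0.37). Ribosomal proteins were enriched less in 1 of 49 (46 adjusted over the list alone, 10 over all genes with the block, median -1.11, adjusted p = 1.14e-21, and adjusted p = 0.39 with an estimated correlation). This gave 249 higher and 196 lower genes, 517 and 428 with the block, 731 and 758 by DESeq2, and 0 in a fit of only the compared libraries. Leaving out enriched s6G libraries 1 and 2 gave 296 and 11, s6G inputs 1 and 2 62 and 0, enriched unlabelled libraries 1 and 2 2370 and 683, and unlabelled inputs 1 and 2 0 and 37. Total counts moved the higher share from 56% to 79.9% and the median of all genes by 0.23.

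Against the APEX-only arm, mitochondrial mRNAs had a median difference of -1.33 with s6G (0 of 13 called, 12 lower adjusted over the list alone, camera adjusted p = 1.04e-14, and adjusted p = 0.435 with an estimated correlation). Translocon genes followed at -0.67 (0 of 27 called, 10 lower adjusted over the list alone, adjusted p = 2.43e-09, and adjusted p = 0.435 with an estimated correlation). Single genes gave 0 edgeR calls (2020 at an unadjusted p under 0.05, DESeq2 422 higher and 387 lower, 0 with the replicate block, n = 2). A fit without the shallowest unlabelled library called 506. APEX only against unlabelled also gave 0 edgeR calls (1748 at an unadjusted p under 0.05, DESeq2 126 and 33, 0 with the block), but 94 and 131 without enriched unlabelled libraries 1 and 2. There, ribosomal proteins had a median difference of -0.71 (0 called, 0 adjusted over the list alone, adjusted p = 3.46e-14, and adjusted p = 0.739 with an estimated correlation).

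In inputs of the LMNB1 construct, ATF3 and JUN were among the genes higher with s6G than in the APEX-only arm. ATF3 rose by 2.22 ± 0.26 (edgeR adjusted p = 0.0111, n = 2), JUN, an immediate-early transcription factor, by 1.64 ± 0.21, RBM15 by 1.86 ± 0.26 and CCNL1 by 1.42 ± 0.21. KIF11, a motor of the mitotic spindle, fell by 1.18 ± 0.19 on the log2 scale and NCAPH, a condensin subunit, by 1.31 ± 0.19. Histone genes lay higher as a list (0 of 22 called, 5 adjusted over the list alone, median 1.83, camera adjusted p = 4.28e-08, and adjusted p = 0.609 with an estimated correlation). Here 18 genes rose and 3 fell. With the replicate block 4623 were called, in a fit without the shallowest unlabelled library 139, and without s6G input 2 only 2, against 1 without each of the other inputs. Total counts moved the higher share from 85.7% to 66.7% and the median of all genes by -0.11.

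Between arms that share no library, called genes overlapped. In the MITO construct, s6G and s4U shared 17 higher genes (0.0494 by independence, 15 of them mitochondrial), s6G and APEX only 28 (0.11, 16 mitochondrial), and s4U and APEX only 17 (0.0426, 15 mitochondrial). The authors' deposited LMNB1 table, with 1012 higher and 2042 lower genes for s6G and 462 and 1230 for APEX only, correlated with the enriched against input fold changes computed here at r = 1 across genes in both arms. With an estimated correlation, the camera calls that held were mitochondrial mRNAs in the 3 labelled MITO arms (0.0102 with s6G, 0.00621 with s4U, 0.0157 with APEX only), lysosomal genes in MITO with s6G (0.0223) and s4U (0.00621), secreted proteins for NES (0.0449), transporters for ERM against NES (0.0122) and in the unlabelled LMNB1 arm (0.0243), and nuclear long RNAs for LMNB1 APEX only (0.0355). With the replicate block added, the mitochondrial mRNAs had 0.352, 0.315 and 0.353 and the lysosomal genes 0.199 and 0.0846. Secreted proteins for NES, transporters in the unlabelled LMNB1 arm and nuclear long RNAs for LMNB1 APEX only lost the call too, with values given beside those results. Of the calls listed here, only transporters for ERM against NES stayed under 0.05 with the block.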

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

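Both tests on SEC61B and the tests on capture and on the bead step were chosen only after the results were seen, and the remaining tests of this part before. In tests of the interaction, MITO enrichment differed from the unlabelled arm for 57 genes with s6G, for 40 with s4U and for 6 with APEX only. LMNB1 enrichment with s6G differed from its unlabelled arm for 445 genes. ERM and NES enrichment differed for 1 gene, SEC61B, in the edgeR fit without a block. When each library was left out, these counts ranged from 0 to 859, 0 to 831, 0 to 901, 0 to 2370 and 0 to 9, with the libraries named beside the comparisons. With the replicate number as a block, ERM against NES gave 393 higher and 559 lower genes. Against unlabelled, the block gave 1573, 1608 and 1055 genes for MITO s6G, s4U and APEX only, and 517 higher and 428 lower for LMNB1 s6G. SEC61B also stood apart in input libraries, which the comparison of enrichments does not use on their own. Its mean CPM in ERM inputs was 10.6 times the mean of the other inputs. Over both groups of 4 ERM libraries, 6 tests of measures per library looked for a library far from the others, and none was above the 95% critical value of Dixon's test.

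SEC61B was higher in every ERM library than in any other, before enrichment as well as after. A candidate source is the construct itself, if it carries SEC61B coding sequence. The lowest ERM input had 7.9 times the CPM of the highest other input, but this level raised the question and so cannot test that source. SEC61A1 and SEC61G stood at 1.04 and 1.53 times the mean of other inputs. Labelling of all translocon transcripts at the ER membrane would raise their class: the highest of the 26 other members, SRPRA, differed by 0.99 (95% interval 0.54 to 1.44) and their median was 0.24, against 2.04 (1.55 to 2.54) for SEC61B. What the construct contains is not in the labels, so the source of the reads and the larger rise after enrichment (2700 to 3450 CPM) stay open.

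Fold changes of nuclear-encoded genes after enrichment were shared between constructs that sit in different places. Across genes, which are not independent replicates, ERM correlated with NES at r = 0.94, with MITO s4U at 0.56, with MITO s6G at 0.52 and with LMNB1 s6G at 0.43, the lowest of the arms with a thionucleoside. In arms without it, r was 0.23 (LMNB1 APEX only), -0.16 (MITO unlabelled), -0.18 (LMNB1 unlabelled) and -0.18 (MITO APEX only). All enriched libraries share the bead step and the added PCR cycles, so the MITO APEX-only value argues against these as the whole cause. The 0.23 of LMNB1 APEX only leaves room for a part. Low values of the unlabelled arms can reflect shallow libraries (123341 and 842177 counts for enriched MITO). It also argues against a bias by gene span as the whole cause that r between ERM and MITO s6G was 0.55 after its trend was removed and 0.52 before (9615 genes, 98.6% with a span). The values are consistent with capture of RNA that carries thionucleoside, in part whatever the construct, and hence of newly made RNA; the design has no ERM or NES arm without s6G, so shared location of the transcripts stays open.

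The ERM result was set against all 35 splits of its 8 libraries into 4 and 4. The real split called 9870 genes, and the highest of the others 0, including the 7 others that part all 4 pairs and the split by depth (1 of 35 as large). Each other split mixes enriched and input libraries, so their difference enters the spread. A count of 0 there says little about chance. With the pairing, only the 8 splits that part all 4 pairs compare, the real one included, too few for a share under 0.05.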

How the results depend on the processing

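Counts of called genes under the alternatives are given here as totals of higher and lower, and the cause was not tested unless stated. Chosen after seeing the data were the fits without the unlabelled MITO arm and without the shallowest unlabelled LMNB1 library, the split of the ERM numbers, the crossed pairing, the swaps of mitochondrial shares within pairs, and the tests of enriched and of input libraries alone. The calls of single named genes had the same direction in all alternatives, leaving out libraries included: 8654 values kept their side of the threshold, 1546 lost it, 122 gained it and 0 reversed. The shallowest library, in the unlabelled MITO arm, held 123341 counts.

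Total counts in place of TMM gave 2815 genes for MITO s6G, 132 for MITO s4U, 1131 for MITO APEX only, 1247 for MITO s6G against unlabelled, 240 for ERM against NES, 61 for LMNB1 s6G against APEX only, 736 for LMNB1 s6G against unlabelled, 4 for LMNB1 APEX only against unlabelled, 0 for the MITO s6G inputs and 9 for the LMNB1 inputs. The median of mitochondrial mRNAs in MITO APEX only was 2.31 instead of 3.05. That of s6G against s4U was -0.03 instead of 0.50, as the median of all genes moved by -0.42. RLE scaling gave 21 for MITO s6G and 0 for MITO s4U against unlabelled, 145 for LMNB1 APEX only and 2 for LMNB1 unlabelled. TMM on nuclear genes gave 10 for LMNB1 unlabelled.

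Without a filter on low counts, the MITO arms gave 81 (s6G), 38 (s4U), 75 (APEX only) and 3421 (unlabelled). The differences gave 1 for s4U against APEX only, 563, 511 and 202 for s6G, s4U and APEX only against unlabelled, and 104 for ERM against NES. LMNB1 gave 386 (APEX only), 375 (unlabelled), 268 (s6G against APEX only), 939 (s6G against unlabelled) and 87 (APEX only against unlabelled). Inputs gave 60 (MITO s6G), 6 (MITO s4U) and 207 (LMNB1). The stricter filter gave 302 for MITO unlabelled, 23 and 0 for MITO s6G and s4U against unlabelled, and 2 for LMNB1 unlabelled. A threshold of 2-fold left 5259 for ERM, since smaller changes no longer count.

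A fit of only the compared libraries has fewer libraries to estimate the spread. It gave 0 for MITO s6G, 75 for MITO APEX only, 320 for MITO unlabelled, and 0 for both MITO s6G and MITO s4U against unlabelled. It gave 3394 for LMNB1 s6G, 1317 for LMNB1 APEX only, 0 for LMNB1 unlabelled, 657 for s6G against APEX only and 0 for s6G against unlabelled, and 2 and 4 for the MITO s6G and LMNB1 inputs. DESeq2 gave 602, 387 and 600 for MITO s6G, s4U and APEX only, 13 and 3 for s6G and s4U against APEX only, and 694, 753 and 456 for the 3 labelled arms against unlabelled. It gave 463 for ERM against NES, 1051 for LMNB1 APEX only, 436 for LMNB1 unlabelled, 809 for s6G against APEX only, 1489 for s6G against unlabelled and 159 for APEX only against unlabelled. For the inputs it gave 180 (MITO s6G), 53 (MITO s4U) and 289 (LMNB1).

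With the replicate number as a block, MITO gave 1033 (s6G), 755 (s4U), 1083 (APEX only) and 3105 (unlabelled), 9 and 17 for s6G and s4U against APEX only, and 1573, 1608 and 1055 for s6G, s4U and APEX only against unlabelled. ERM against NES gave 952, LMNB1 APEX only 674, LMNB1 s6G against unlabelled 945, and the inputs 0 (MITO s6G) and 4623 (LMNB1). Where the total moved less, the higher genes went to 1380 for LMNB1 s6G and the lower from 2 to 0 for LMNB1 unlabelled. The block moved no other total by more than 1.5 times. Deviations of the MITO inputs correlated at -0.49 (s6G with APEX only) and -0.68 (s4U with APEX only), and crossing the APEX-only numbers gave 2790 and 1199 genes. LMNB1 inputs correlated at 0.64 between arms.

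ERM numbers 1 and 2 alone gave 778 genes against NES, and numbers 3 and 4 alone 1482. Enriched ERM against enriched NES libraries gave 935, and inputs against inputs 137. Without the shallowest unlabelled library, LMNB1 gave 3660 (s6G), 992 (APEX only), 506 (s6G against APEX only) and 139 (inputs). Without the unlabelled MITO arm, the MITO s6G inputs gave 13.

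Leaving out each library, where the lone library of a group was assumed to vary like the other groups, gave 13 to 50 genes for MITO s6G, 0 to 18 for s4U, 5 to 23 for APEX only and 0 to 1723 for unlabelled. It gave 0 to 0 for the 3 differences among labelled MITO arms, and 0 to 859, 0 to 831 and 0 to 901 for s6G, s4U and APEX only against unlabelled. ERM ranged from 9307 to 9665, NES from 6986 to 7211 and their difference from 0 to 9. LMNB1 ranged from 784 to 1176 (s6G), 0 to 0 (APEX only), 0 to 1064 (unlabelled), 0 to 0 (s6G against APEX only), 0 to 2370 (s6G against unlabelled) and 0 to 131 (APEX only against unlabelled). Inputs ranged from 0 to 1 (MITO s6G), 0 to 0 (MITO s4U) and 1 to 2 (LMNB1).

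The mitochondrial share of the authors' deposited TPM, which divides by gene length, was 86.8% (s6G), 81% (s4U), 82.6% (APEX only) and 33% (unlabelled) after enrichment and 35.7%, 30%, 32.4% and 37.4% in the inputs. Counting the 13 mRNAs alone, the share of counts in the inputs was 5.15% (s6G), 3.66% (s4U) and 4.61% (unlabelled).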

Other observations

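The fits of MITO and LMNB1 inputs together, with the construct as a term, and the sets drawn within construct and number were chosen after seeing the data, and the tests of neighbouring genes, of gene span and of the splits before their results were seen. Single genes named from these fits lie outside the fixed rule and were chosen after their values were seen. With s6G, whole-cell RNA differed from that of cells without a thionucleoside at 1731 higher and 2200 lower genes of 14239 (edgeR, n = 4 against 8; DESeq2 2296 and 2132). All 15 tested replication-dependent histone genes rose (15 adjusted over the list alone, median log2 fold change 2.08, camera adjusted p = 5.53e-18, and adjusted p = 0.116 with an estimated correlation), such as H2BC5 (2.62 ± 0.28, adjusted p = 1.83e-05) and the linker histone gene H1-2 (1.81 ± 0.17). Cytosolic ribosomal protein genes rose in 47 of 49 cases (47 adjusted over the list alone, median 0.53, adjusted p = 4.53e-24, and adjusted p = 0.338 with an estimated correlation), and nuclear genes of the respiratory chain in 26 of 39 (31 adjusted over the list alone, median 0.40, adjusted p = 8.61e-10, and adjusted p = 0.402 with an estimated correlation). Mitochondrial mRNAs rose in 8 of 13 (8 adjusted over the list alone, median 0.48, adjusted p = 0.000611, and adjusted p = 0.475 with an estimated correlation). Of the immediate-early genes 15 rose and 2 fell of 39 (16 and 4 adjusted over the list alone, median 0.25, adjusted p = 0.0028, and adjusted p = 0.338 with an estimated correlation). Single stress genes rose, among them ATF3 (2.28 ± 0.18, adjusted p = 1.82e-06), JUN (1.92 ± 0.17) and GADD45A, a growth arrest gene (1.00 ± 0.14), as did RBM15 (1.92 ± 0.12). As lists, p53 targets (3 higher and 3 lower of 24, 3 and 3 adjusted over the list alone, median -0.06, adjusted p = 0.927) and heat shock genes (1 and 2 of 19, 1 and 2 adjusted over the list alone, median -0.08, adjusted p = 0.927) were not called. Targets of ATF4 (6 and 2 of 24, 8 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.0207, and 0.736 with an estimated correlation) and of NRF2 (8 and 2 of 20, 9 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.0364, and 0.402 with an estimated correlation) lay higher.

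With s4U at the same dose and time, 141 genes rose and 544 fell (DESeq2 273 and 677; n = 2 against 8). ATF3 lay at -0.32 ± 0.26 (edgeR adjusted p = 0.614) and JUN at -0.46 ± 0.25 (adjusted p = 0.382). Histone genes lay at a median of 0.68 (0 of 15 called, 0 adjusted over the list alone, camera adjusted p = 0.00712, and adjusted p = 0.904 with an estimated correlation), and ribosomal proteins rose in 4 of 49 cases (39 adjusted over the list alone, median 0.39, adjusted p = 1.8e-19, and adjusted p = 0.636 with an estimated correlation). Between s6G and s4U inputs, 145 genes were higher and 173 lower. APEX-only and unlabelled inputs differed at 0 genes by edgeR (129 at an unadjusted p under 0.05) and at 0 by DESeq2 (173).

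The s6G effect appeared in both constructs, which share no library. Fitted apart, MITO and LMNB1 fold changes correlated at r = 0.84 (rho = 0.83) across 10303 genes, which are not independent replicates. Higher in both were 141 genes (6.6 by independence) and lower in both 162 (10.3), with 0 in opposite directions. Leaving out each input gave 3073 to 4117 genes, and total counts gave 1207 higher and 3103 lower. Of 100 drawn sets of 4 of the 12 inputs other than s4U, 1 called as many genes as the s6G inputs, the real one with 3975, and the highest other called 596. That set held 4 libraries of replicate 1, which points to a structure by replicate number. Other sets took 1 library from each construct and number. Of these 81 sets, 1 called as many, the real one, and the highest other called 0. Sets with 3 s6G inputs called 0 as well, so a count of 0 says little about chance. The sets were chosen after the data were seen, and number 1 of the MITO s6G and APEX-only inputs deviated in opposite ways (r = -0.49). The numbers thus do not hold a batch fixed there, and this draw does not exclude chance. With the replicate number within construct as a term, 2064 genes rose and 2831 fell. The trend of fold changes on gene span was rho = -0.35 for s6G and -0.47 for s4U, and after removing each input's trend 3260 of 13532 genes were called, against 3778 before, so span bias is not the whole of it.

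Among genes close to silent without a thionucleoside (under 2 CPM), some rose strongly with s6G. Fold changes from so low a level are easily large, and these genes were ranked among such genes only. MYO1G, a myosin gene of blood cells, had 12.7 to 21.9 CPM in s6G inputs of MITO and LMNB1 and 10.4 to 25.1 CPM in ERM and NES inputs, against 0.477 to 0.761 CPM with s4U and 0 to 0.712 CPM without thionucleoside (6.04 ± 0.42, edgeR adjusted p = 8.19e-07). PRR18 (6.32 ± 0.55) and EVPL (6.12 ± 0.55) rose likewise. MYO1G lies 4008 bp from SNHG15, which had 68.8 CPM, while PRR18 lies 11336 bp from SFT2D1 (51.2 CPM) and EVPL 11479 bp from SRP68 (226.5 CPM), both outside the 10 kb tested below. A hypothesis is that transcripts of expressed neighbours may run on into such genes. The test took 837 genes with some counts but a mean under 2 CPM without thionucleoside, and with coordinates on an autosome or X. Genes without any count there were left out. All 837 had passed the expression filter over all MITO and LMNB1 inputs. Inputs with s6G or s4U count in that filter, so genes can have entered through their rise. Hence 130 of 837 is no share of all low genes, and the odds ratios below hold for this selected set only. With s6G, 130 rose at least 4-fold, and 60% of these lay within 10 kb of a gene of at least 20 CPM. Of the 707 others, 42.9% did (Fisher's exact odds ratio 2, p = 0.000371). Adjusted for level, gene length and local gene density, the odds ratio was 1.87 (95% interval 1.07 to 3.26). With s4U it was 2.49 (1.09 to 5.69), with 33 genes raised. The test is consistent with reads from neighbours for part of these genes, and induction of the genes themselves was not tested. Without the strand or the position of reads in these data, where they start cannot be seen here.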
